A study of Mus musculus with 4 samples.

How the data were processed

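The data were RNA-seq libraries of snap-frozen MC38 tumours from mice injected daily with saline or vanoxerine, 2 libraries per group. Per the labels' protocols, total RNA was purified, libraries were made with the TruSeq RNA v2 kit, and they were sequenced on a NextSeq 500. Per the submitters' processing notes, the tools were fastp, Salmon 1.3.0 and DESeq2, and the genome build was GRCm38. The annotation release, the read length and the settings of these tools are not given in the sources used here. The strand setting of the counting is not given either, so overlapping and antisense genes cannot be separated with certainty.

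For each library the authors deposited Salmon's estimated count, TPM and effective length for 140992 transcripts. Per the file headers, the estimated count is the number of reads that Salmon assigned to a transcript, not normalized, and TPM is scaled to transcript length and to the library total. The authors' deposited table of the comparison gives, per the file headers, a base mean per gene (a signal averaged over libraries after the authors' normalization), a log2 fold change with its standard error, a p-value and an adjusted p-value. That table also has 4 columns of per-library FPKM values. Their names match none of the samples, and they were not used here.

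Transcripts were assigned to genes with GENCODE mouse release M21 on GRCm38, and 139791 of 140992 transcripts had a gene there. They held between 99.56% and 99.63% of the reads of each library. The estimated counts were summed over the transcripts of each of 54115 genes and rounded to whole numbers. Total estimated reads were 75748162 and 70274527 in the saline libraries and 70564325 and 67289273 in the vanoxerine libraries. Salmon divides reads that match several transcripts among them by estimate, so values of near-identical genes are less certain than the depth implies.

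The comparison used edgeR 4.0.16 under R 4.3.3, with TMM factors, its default low-count filter (minimum count 10, minimum total 15) and the quasi-likelihood test of vanoxerine against saline, without a block. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and 18758 genes were tested. Levels are given as CPM (read counts scaled to library size and TMM factor), as mean ± SD over the 2 libraries of a group. Fold changes are on the log2 scale with their standard error (SE), taken from the test's F statistic. Before the data were examined, 32 gene lists were fixed and tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The 32 lists make up 1 family for the adjustment. Another 6 lists were chosen after the data were seen.

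The genes named were also set by a rule before the data were examined. It takes up to 10 genes per direction with the largest log2 fold change among those called, with a mean log2 CPM of at least 1, groups that do not overlap, and a symbol that is neither a predicted gene model nor a pseudogene. It adds up to 4 members with the smallest p of each list described, and 10 genes chosen in advance, among them Slc6a3, Ehmt2, Ehmt1, Lgr5, Cd8a, Ifit1, Isg15, H2-K1 and Mki67. Of the genes this rule takes, 3 are not reported here, and the counts of named genes leave them out. For a gene with no read in 1 group, a fold is a lower bound against 3 reads in each library, and it covers counting error only.

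On simulated counts for the same 18758 genes, with 200 changed in 2 against 2 libraries, the test recovered 38.8% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 74.2% of those changed 4-fold. It called 3 unchanged genes, and camera called 0 unchanged lists. The simulated genes varied independently of each other, so the simulation does not test camera on lists of correlated genes. It also changed far fewer genes than the 6916 called in the data. Both groups were given the same dispersion (spread of counts beyond sampling noise). In the data the common dispersion, over genes with a mean of at least 10 CPM, was 0.0099 in saline and 0.0014 in vanoxerine. The recovery rates therefore do not carry over to these data. With 2 against 2 libraries there are 3 splits of the samples, and the smallest two-sided exact permutation p is 0.333.

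Alternatives were other scalings (median of ratios, upper quartile, library totals), no low-count filter, a mean CPM of at least 1, an adjusted p under 0.1, DESeq2 1.42.0, limma-voom, an average transcript length offset, log2(TPM + 1) with limma-trend, protein-coding genes only, the replicate number as a block, and leaving out each library. Where a library is left out, its group has 1 library, which is assumed to vary like the other group.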

Results

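The transcriptomes of MC38 tumours, grown in mice from an injected mouse colon adenocarcinoma cell line, were compared between 2 saline and 2 vanoxerine libraries. Vanoxerine is an inhibitor of the dopamine transporter and was given intraperitoneally at 25 mg/kg, as 10 daily injections. The libraries held 67289273 to 75748162 estimated reads. The mitochondrial share of reads was 3.49% and 2.59% in saline and 2.79% and 2.74% in vanoxerine, and pseudogenes took 3.63% and 2.99% against 2.64% and 2.60%.

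Libraries of 1 group resembled each other closely but differed by more than sampling noise. The median absolute log2 ratio between replicates was 0.099 in saline and 0.047 in vanoxerine, over genes with a mean of at least 10 CPM, and 0.27 between the groups. The mean chi-square per gene was 37.7 between the saline libraries and 11.9 between the vanoxerine libraries, where 1 is the value of sampling noise alone, so they were counted as separate libraries. The labels do not say that the libraries of a group came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical.

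The comparison asked how MC38 tumours respond to vanoxerine. Vanoxerine tumours had higher levels of macrophage, dendritic cell and MHC class II transcripts, and lower levels of fibroblast, endothelial, erythroid and neutrophil transcripts, than saline tumours. These lists were called by camera, and with an estimated correlation none of the 32 lists was (smallest adjusted p = 0.353). The complement gene C1qa rose 8.93-fold, from 83.2 ± 1.60 to 743 ± 14.4 CPM (mean ± SD, n = 2), and the macrophage mannose receptor gene Mrc1 rose 11.7-fold, from 23.8 ± 1.90 to 278 ± 2.82 CPM. H2-Ab1, which encodes an MHC class II chain, rose 7.66-fold, from 29.5 ± 0.844 to 226 ± 0.929 CPM. The collagen gene Col3a1 was 2.13-fold lower, at 233 ± 4.88 CPM in saline and 109.5 ± 3.43 CPM in vanoxerine, and the endothelial gene Plvap 4.05-fold lower, at 21.8 ± 0.529 CPM in saline and 5.39 ± 0.106 CPM in vanoxerine. Proliferation genes were not called as a list, and Mki67 stood at 259.6 ± 2.90 CPM in saline and 262 ± 1.28 CPM in vanoxerine.

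Of 18758 genes tested, 6916 (36.9%) were called by edgeR, 3933 higher and 2983 lower in vanoxerine, so that 56.9% of the calls were higher. A log2 fold change of at least 1 in size was found for 1646 of them, 1034 higher and 612 lower. Both vanoxerine libraries lay on the same side of both saline libraries for 70.7% of genes tested, against 33.3% by chance. The split of calls depended on the processing. With a change of scaling alone, 39.0% of calls were higher with upper-quartile factors (2895 higher, 4525 lower), 50.9% with library totals and 56.8% with median-of-ratios factors. With log2(TPM + 1) and limma-trend, where scaling, length, transform and test change together, 82.5% were higher (4094 higher, 870 lower). Without vanoxerine replicate 1 or 2 the count of calls was 3235 or 3107, without saline replicate 1 or 2 it was 9708 or 9595, and with an average transcript length offset it was 4309. The count of genes lower by at least 1 on the log2 scale was 283 to 1059 without 1 library and 149 with log2(TPM + 1).

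**Figure D1:**
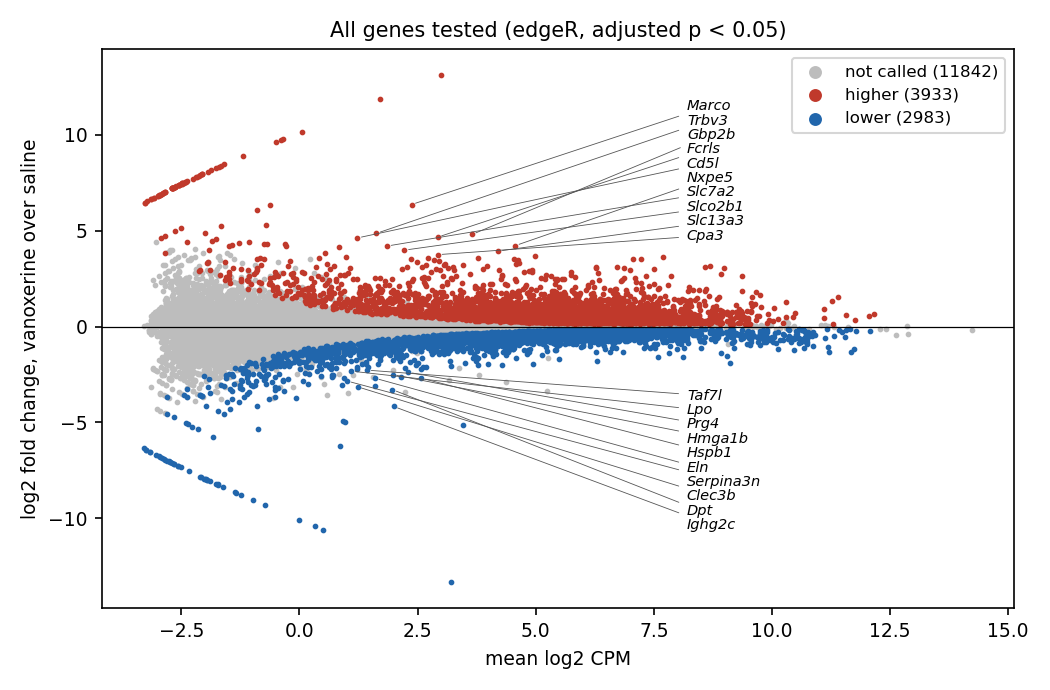
Each point is 1 of the 18758 genes tested, with its mean log2 CPM on the horizontal axis and the log2 fold change of vanoxerine over saline on the vertical axis. The 3933 genes called higher are red, the 2983 called lower are blue, and the diagonal rows at the left edge are genes with no reads in 1 group, whose fitted fold change has no fixed size; lines mark the 20 genes with the largest changes under the naming rule.

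Among the largest rises, Marco, a scavenger receptor gene of macrophages (chromosome 1, 120474538 to 120505024, reverse strand, GRCm38), went from 0.122 ± 0.0131 to 10.2 ± 0.803 CPM, a log2 fold change of 6.37 ± 0.23 (SE). Other genes of macrophages and microglia were Fcrls, with 4.67 ± 0.33, and Cd5l, with 4.62 ± 1.05. Cd5l had no reads in 1 saline library, and its edgeR adjusted p of 0.0179 became 0.142 with DESeq2, the highest of 15 alternatives, whose lowest was 1.65e-11. The transporter genes Slc7a2 (4.20 ± 0.37), Slco2b1 (3.99 ± 0.20) and Slc13a3 (3.94 ± 0.17) also rose, as did Nxpe5 (4.22 ± 0.093). Cpa3, a protease of mast cell granules, rose from 1.05 ± 0.350 to 14.2 ± 0.802 CPM, or 13.5-fold. Gbp2b, an interferon-inducible GTPase gene with near-identical family members, rose from 0.862 ± 0.206 to 24.2 ± 0.970 CPM. The T cell receptor variable segment Trbv3 (chromosome 6, 41048290 to 41048828, forward strand) rose from 0.202 ± 0.0283 to 5.95 ± 0.450 CPM.

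The largest falls included genes of connective tissue. Dpt, which encodes the matrix protein dermatopontin (chromosome 1, 164796644 to 164824266, forward strand), went from 7.02 ± 0.342 to 0.717 ± 0.0690 CPM, a log2 fold change of -3.29 ± 0.21. Clec3b (-3.14 ± 0.30), the elastin gene Eln (-2.69 ± 0.24) and the lubricin gene Prg4 (-2.38 ± 0.19) fell as well. Ighg2c, an immunoglobulin constant segment, was 18.0-fold lower, at 7.47 ± 1.26 CPM in saline and 0.414 ± 0.00638 CPM in vanoxerine, and the acute-phase gene Serpina3n was 7.16-fold lower. Hspb1, a small heat shock protein gene, fell from 10.3 ± 0.413 to 1.59 ± 0.363 CPM. Lpo (-2.32 ± 0.32) and Taf7l (-2.27 ± 0.35) also fell, and so did Hmga1b (-2.50 ± 0.26), a near-identical copy of Hmga1 whose reads are uncertain. The edgeR adjusted p for these falls was highest for Taf7l, at 0.00438.

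Macrophage and monocyte markers rose in 19 of 21 genes and fell in 2, with a median log2 fold change of 2.01 (camera adjusted p = 1.94e-09; adjusted p = 0.353 with an estimated correlation). The complement genes C1qc (3.12 ± 0.045), C1qa (3.16 ± 0.045; chromosome 4, 136895917 to 136898803, reverse strand) and C1qb (2.76 ± 0.054) and the receptor gene Mrc1 (3.55 ± 0.069; chromosome 2, 14229392 to 14332057, forward strand) had the smallest p. The 2 that fell, named after their values were seen, were the monocyte gene Ly6c2 (-0.32 ± 0.048) and the osteopontin gene Spp1 (-0.22 ± 0.045). MHC class II genes rose in 11 of 12, by a median of 1.51 (camera adjusted p = 2.93e-06; adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone, 11 rose and 1 fell. H2-Ab1 (2.94 ± 0.051; chromosome 17, 34257689 to 34269419, forward strand), H2-Aa (2.66 ± 0.056) and H2-Eb1 (2.54 ± 0.073) encode class II chains, whose reads related genes can share, and Ctss (1.66 ± 0.044) encodes a protease of antigen processing. Dendritic cell markers rose in 11 of 15 genes and fell in 1, by a median of 1.49 (camera adjusted p = 1.98e-04; adjusted p = 0.484 with an estimated correlation). Cd86, a costimulatory ligand gene, rose from 20.7 ± 0.440 to 61.3 ± 0.610 CPM, Itgax rose by 1.13 ± 0.070, Clec10a by 2.14 ± 0.15 and the migration receptor gene Ccr7 by 1.49 ± 0.14. Whether dendritic cells or macrophages held these transcripts was not tested, and the macrophage list median was 2.01.

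**Figure D2:**
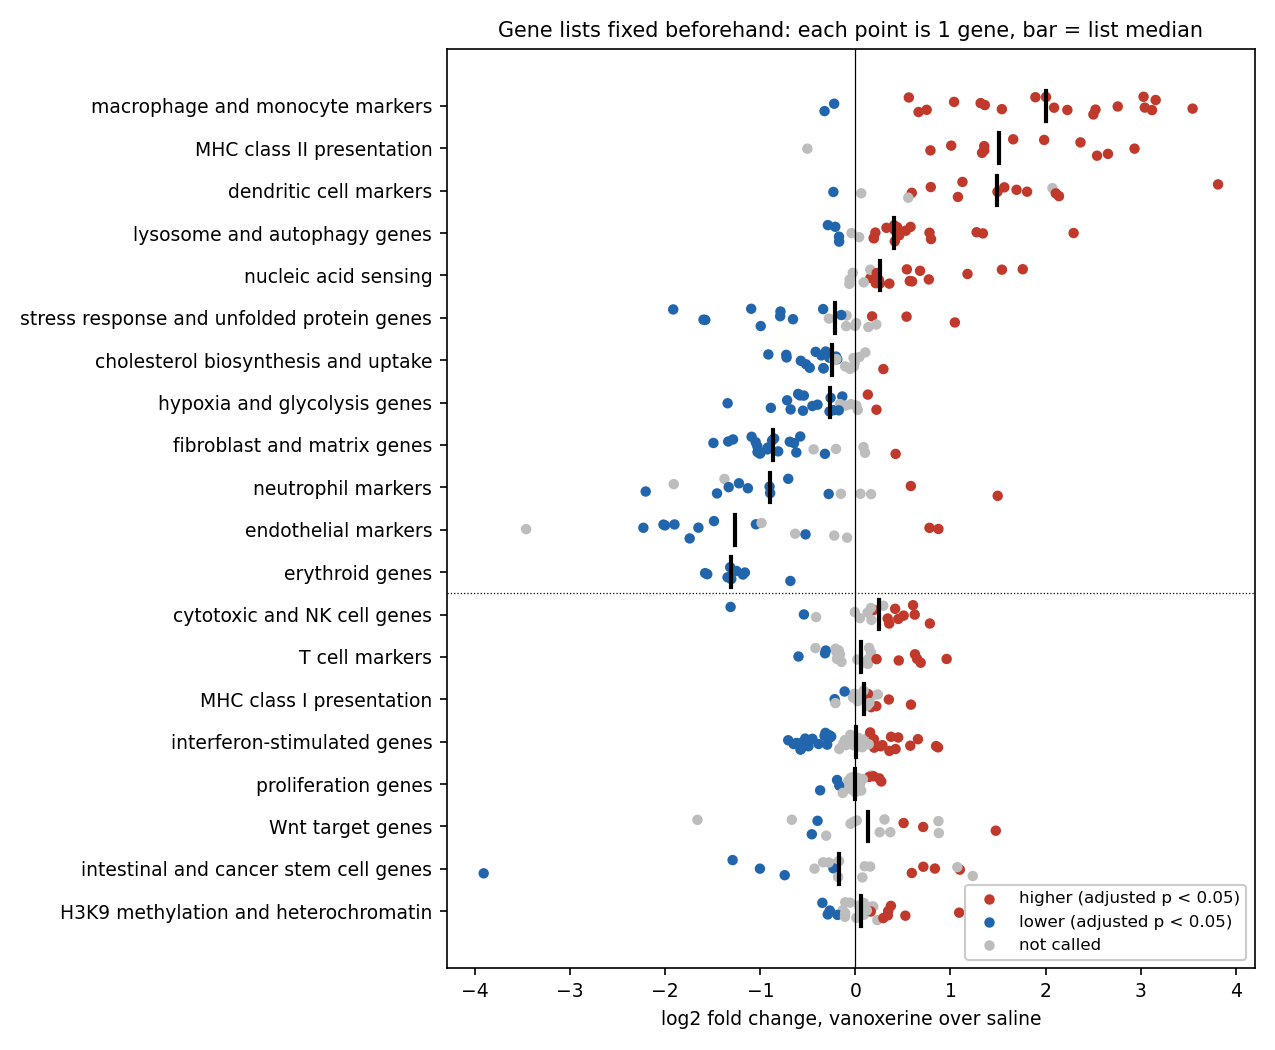
Log2 fold change of vanoxerine over saline for each tested gene of 20 lists, red if called higher, blue if called lower and grey if not called, with a black bar at the list median. The 12 lists called by camera are above the dotted line, from macrophage markers (median 2.01) to erythroid genes (median -1.31), and 8 of the lists not called are below it.

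In the same libraries, lysosome and autophagy genes rose in 17 of 23 and fell in 4, by a median of 0.41 (camera adjusted p = 0.00214; adjusted p = 0.477 with an estimated correlation). The cathepsin genes Ctsb (1391 ± 4.26 to 3526 ± 28.0 CPM) and Ctsd (731 ± 38.1 to 1769 ± 12.8 CPM), the lysosomal lipase gene Lipa (2.30 ± 0.073) and the hexosaminidase gene Hexa (0.80 ± 0.053) rose, next to the macrophage list median of 2.01. Nucleic acid sensing genes rose in 14 of 19 and fell in 0 (5 did not pass the test), by a median of 0.26 (camera adjusted p = 4.26e-04; adjusted p = 0.353 with an estimated correlation). Tlr9 (1.76 ± 0.087) and Tlr7 (1.54 ± 0.081), endosomal sensors of DNA and RNA, the nuclease gene Samhd1 (0.77 ± 0.042) and the transcription factor gene Irf5 (1.18 ± 0.074) led this list. Tlr7 was at 0.84 with the length offset (adjusted p = 0.548) and at 1.56 with log2(TPM + 1) (adjusted p = 0.309), no call in either, and at 0.096 in the authors' deposited table (adjusted p = 0.656).

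Fibroblast and matrix genes fell in 19 of 24 and rose in 1, by a median of -0.87 (camera adjusted p = 1.42e-07; adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone, 20 fell and 1 rose. Col3a1 (-1.09 ± 0.048; chromosome 1, 45311538 to 45349706, forward strand), Col6a1 (-0.92 ± 0.045), Col6a2 (-1.0 ± 0.054) and the proteoglycan gene Dcn (-0.93 ± 0.050) had the smallest p. Endothelial markers fell in 9 of 16 and rose in 2, by a median of -1.27 (camera adjusted p = 5.16e-04; adjusted p = 0.360 with an estimated correlation). Adjusted over the list alone, 10 fell and 2 rose. Plvap (-2.02 ± 0.10; chromosome 8, 71497765 to 71511752, reverse strand), the VE-cadherin gene Cdh5 (-1.05 ± 0.085) and the junction gene Esam (-1.90 ± 0.16) fell, whereas Pecam1 (0.87 ± 0.048), which leukocytes also express, rose. Erythroid genes fell in 9 of 9, by a median of -1.31 (camera adjusted p = 9.27e-06; adjusted p = 0.353 with an estimated correlation). The haemoglobin gene Hbb-bs went from 4649.6 ± 152 to 1881 ± 52.6 CPM, Alas2, which starts haem synthesis in red cell precursors, from 164 ± 13.1 to 65.8 ± 0.121 CPM, and Hba-a1 (-1.18 ± 0.065) and Hba-a2 (-1.16 ± 0.036), whose near-identical sequences share reads, fell too. Neutrophil markers fell in 9 of 16 and rose in 2, by a median of -0.90 (camera adjusted p = 0.00628; adjusted p = 0.360 with an estimated correlation). Adjusted over the list alone, 10 fell and 2 rose. S100a9 (-1.13 ± 0.061), S100a8 (-0.90 ± 0.053) and G0s2 (-1.33 ± 0.062) fell, and the gelatinase gene Mmp9 (1.5 ± 0.11) rose.

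Hypoxia and glycolysis genes fell in 15 of 22 and rose in 2, by a median of -0.27 (camera adjusted p = 4.26e-04; adjusted p = 0.473 with an estimated correlation). Adjusted over the list alone, 17 fell and 2 rose. With log2(TPM + 1) the hypoxia median was -0.14, with 4 genes higher and 6 lower (camera adjusted p = 0.0170). The glucose transporter gene Slc2a1 fell from 357 ± 6.44 to 217 ± 0.0143 CPM, and Ankrd37 (-1.34 ± 0.081), Ndrg1 (-0.68 ± 0.042) and the phosphofructokinase gene Pfkl (-0.54 ± 0.044) fell with it. Cholesterol biosynthesis and uptake genes fell in 14 of 24 and rose in 1, by a median of -0.25 (camera adjusted p = 0.00105; adjusted p = 0.353 with an estimated correlation). Fdft1, the squalene synthase gene, went from 55.1 ± 1.83 to 29.2 ± 0.471 CPM, Fdps fell by 0.73, Sqle by 0.52, and Cyp51 by 0.48 on the log2 scale. With log2(TPM + 1) the cholesterol median was -0.0077, with 2 genes higher and 4 lower (camera adjusted p = 0.0492), and 7 genes fell with the length offset and 6 without either vanoxerine library. Stress response and unfolded protein genes fell in 10 of 20 and rose in 3, by a median of -0.21 (camera adjusted p = 0.0176; adjusted p = 0.360 with an estimated correlation). The chaperone genes Hspa1b (874 ± 61.1 to 232 ± 11.6 CPM) and Hspa1a (-1.60 ± 0.050), near-identical neighbours whose reads are uncertain, and Dnajb1 (-1.58 ± 0.043) fell, and the haem oxygenase gene Hmox1 (1.05 ± 0.038) rose. With log2(TPM + 1) the stress median was -0.011, with 4 genes higher and 7 lower (camera adjusted p = 0.0463).

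**Figure D3:**
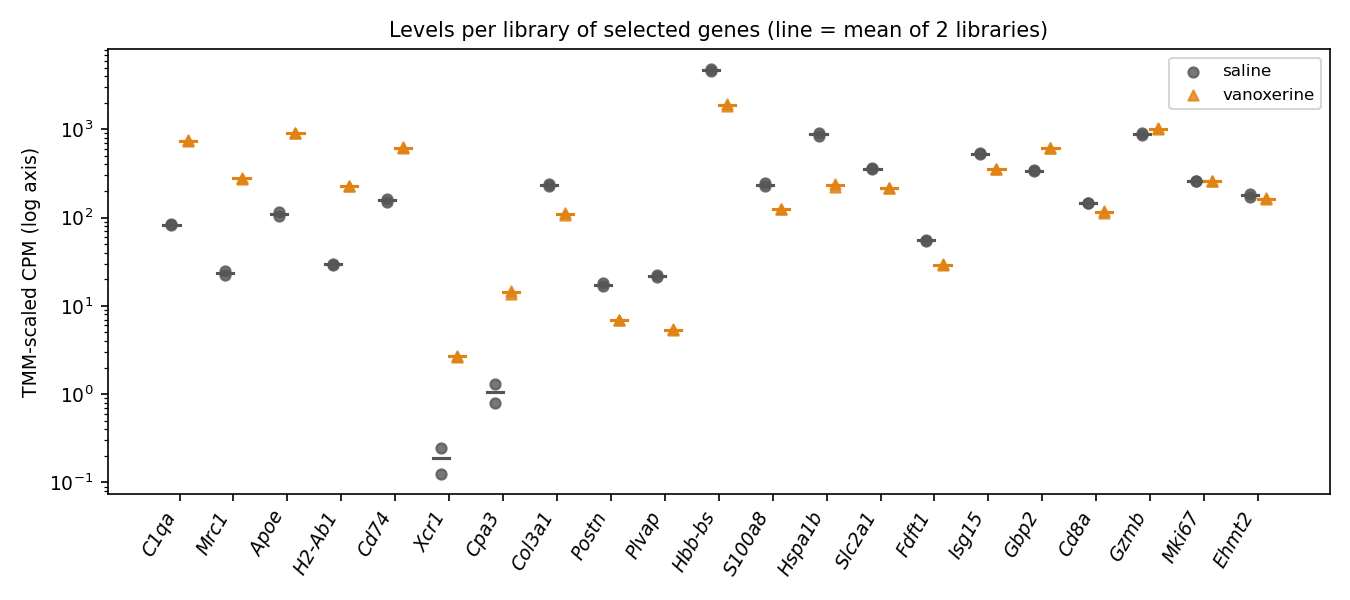
TMM-scaled CPM on a log axis for 21 genes, with 1 point per library (circles for saline, triangles for vanoxerine, 2 each) and a line at the mean of each group. C1qa goes from 83.2 to 743 CPM and Plvap from 21.8 to 5.39 CPM, while the Mki67 means are 259.6 and 262 CPM.

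The other 20 lists were not called by camera in the main test, though camera called 10 of them under at least 1 alternative, 9 of these with log2(TPM + 1), and fry called 12, and for those of lymphocytes and interferon the members went both ways. T cell markers rose in 6 of 22 and fell in 3 (camera adjusted p = 0.778), with Cd28 (0.69 ± 0.080) and Trbc1 (0.63 ± 0.066) higher. The CD8 genes Cd8b1 (-0.60 ± 0.067) and Cd8a, from 146 ± 0.955 to 117 ± 4.58 CPM, fell. Cytotoxic and NK cell genes rose in 9 of 18 and fell in 2 (camera adjusted p = 0.0674). The perforin gene Prf1 (0.42 ± 0.038), Klrk1 (0.45 ± 0.046) and the granzyme gene Gzmc (0.51 ± 0.056) rose, while the interferon gamma gene Ifng fell from 30.1 ± 1.73 to 12.1 ± 0.684 CPM. Checkpoint and regulatory T cell genes rose in 8 of 16 and fell in 3 (camera adjusted p = 0.118), or 9 and 3 adjusted over the list alone. The PD-L1 gene Cd274 rose from 201 ± 0.677 to 378 ± 10.3 CPM, with Entpd1 (0.98 ± 0.063), Havcr2 (0.77 ± 0.054) and Il2ra (0.62 ± 0.071). Interferon-stimulated genes rose in 14 of 46 and fell in 16 (camera adjusted p = 0.612), or 15 and 16 adjusted over the list alone. This split moved with the processing: 8 rose and 22 fell with upper-quartile factors, and 21 rose and 6 fell with log2(TPM + 1). Gbp2 rose from 341 ± 3.91 to 614 ± 8.39 CPM, whereas Usp18 (-0.71 ± 0.042), Bst2 (-0.65 ± 0.044) and Isg15, from 530.1 ± 5.19 to 355 ± 4.33 CPM, fell, and Ifit1 was at 242 ± 33.0 CPM in saline and 234 ± 1.93 CPM in vanoxerine (edgeR adjusted p = 0.692). Ifit1 was called higher without saline replicate 1 and lower without saline replicate 2. For this list the median was 0.01, the mean -0.03 and the camera direction down.

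MHC class I presentation genes rose in 5 of 19 and fell in 2 (camera adjusted p = 0.253), or 7 and 2 adjusted over the list alone. With upper-quartile factors 2 rose and 5 fell, and with log2(TPM + 1) 13 rose and 1 fell. H2-T23 (0.58 ± 0.056), H2-Q7 (0.35 ± 0.041) and the class I transactivator gene Nlrc5 (0.22 ± 0.045) rose and Psmb10 (-0.22 ± 0.048) fell, with reads shared among H2 genes. H2-K1 went from 3324 ± 0.508 to 3073 ± 6.09 CPM (-0.11 ± 0.028), a fall whose sign turned with log2(TPM + 1), at 0.041. Chemokines and inflammatory cytokines rose in 12 of 27 and fell in 7 (camera adjusted p = 0.118). The monocyte attractant genes Ccl8, from 20.9 ± 1.73 to 245 ± 0.490 CPM, and Ccl7 (0.89 ± 0.044), the chemokine gene Cxcl16 (2.15 ± 0.051) and Tgfb1 (0.93 ± 0.046) rose. Genes of p53 targets and apoptosis rose in 11 of 21 and fell in 2 (camera adjusted p = 0.118), with Bcl2l11 (1.06 ± 0.050), Mdm2 (0.94 ± 0.046) and Cdkn1a (0.44 ± 0.042) higher and Gadd45a (-0.85 ± 0.069) lower. Immediate early genes rose in 8 of 16 and fell in 3 (camera adjusted p = 0.0729), among them Fosb (1.24 ± 0.041), Egr2 (1.46 ± 0.061), Nr4a3 (1.14 ± 0.060) and Klf2 (0.93 ± 0.064), all higher.

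Lists chosen for tumour cell programmes were not called either, and which cells of the tumours carried the changes of their members was not tested. Intestinal and cancer stem cell genes rose in 4 of 20 and fell in 5 (camera adjusted p = 0.582), or 4 and 7 adjusted over the list alone. Sox9 fell from 84.9 ± 2.21 to 42.3 ± 0.680 CPM, while Klf4 (1.10 ± 0.064), Cd44 (0.71 ± 0.040) and Aldh1b1 (0.84 ± 0.10) rose, and the stem cell marker gene Lgr5 had 8 reads in all and was not tested. Wnt target genes rose in 3 of 16 and fell in 2 (camera adjusted p = 0.582), with Tcf7l2 (1.48 ± 0.11) and Ccnd1 (0.51 ± 0.052) higher and Jun (-0.40 ± 0.040) and Myc (-0.46 ± 0.052) lower. Genes of H3K9 methylation and heterochromatin rose in 7 of 27 and fell in 5 (camera adjusted p = 0.582). The H3K9 methyltransferase gene Ehmt2 was at 179.8 ± 9.35 CPM in saline and 164 ± 1.59 CPM in vanoxerine (edgeR adjusted p = 0.10) and its partner Ehmt1 at 34.5 ± 2.19 CPM in saline and 36.0 ± 0.924 CPM in vanoxerine (adjusted p = 0.568), and neither was called in the main test. The DNA methyltransferase gene Dnmt3a (1.09 ± 0.076) and Pphln1 (0.53 ± 0.054) rose and Cbx1 (-0.35 ± 0.046) fell, while Atf7ip rose by 0.34 ± 0.052 but was at -1.03 with the length offset and -0.52 with log2(TPM + 1). Proliferation genes rose in 4 of 25 and fell in 3 (camera adjusted p = 0.979), or 2 and 0 adjusted over the list alone. Bub1b (0.27 ± 0.055), Ccna2 (0.25 ± 0.053) and Mcm4 (0.19 ± 0.049) rose, Tyms (-0.37 ± 0.10) fell, but was at 0.0090 with log2(TPM + 1) and also lost the call with the length offset and without either vanoxerine library, and the list median was negative where the mean and the camera direction were positive. With log2(TPM + 1) proliferation genes were called higher (camera adjusted p = 0.0489), with 8 rising and 0 falling. With upper-quartile factors 0 rose and 6 fell, by a median of -0.135, without a list call (camera adjusted p = 0.177). Epithelial-mesenchymal transition genes rose in 6 of 17 and fell in 6 (camera adjusted p = 0.609), or 7 and 7 adjusted over the list alone, with Tgfbi (1.45 ± 0.046), Zeb2 (1.22 ± 0.054) and Itgb3 (0.95 ± 0.049) higher and Snai1 (-1.17 ± 0.079) lower. Epithelial genes rose in 3 of 15 and fell in 1 (camera adjusted p = 0.253), with Cdh1 (1.09 ± 0.11), Epcam (1.03 ± 0.23) and Krt19 (1.69 ± 0.48) higher and Cldn4 (-1.83 ± 0.46) lower.

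The dopamine transporter gene Slc6a3, the known target of vanoxerine, had 1 read over the 4 libraries and was not tested. Of the dopamine handling and receptor genes, 8 of 17 had reads enough to test, 1 rose and 2 fell (camera adjusted p = 0.582). Slc18a2, a vesicular monoamine transporter gene, went from 2 reads over both saline libraries to 78 over both vanoxerine libraries, a ratio of 42.6 (95% exact counting interval 11.4 to 358). The cell type behind these reads was not tested. Maoa (-0.25 ± 0.070), which breaks dopamine down, fell, but was at 0.0022 with log2(TPM + 1) and also lost the call with DESeq2, with the length offset and without either vanoxerine library, and Slc18a1 was at 0.230 ± 0.0270 CPM in saline and 0.691 ± 0.160 CPM in vanoxerine without passing the test.

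Markers of other tissues that a tumour sample could hold gave no list call in the main test. Under alternatives camera called skeletal muscle markers lower without a filter (adjusted p = 0.0396), at a mean CPM of at least 1 (adjusted p = 0.0479) and with log2(TPM + 1) (adjusted p = 0.0489), and skin keratinocyte markers lower at a mean CPM of at least 1 (adjusted p = 0.0314) and with log2(TPM + 1) (adjusted p = 0.0268), whereas fry called the keratinocyte list higher (adjusted p = 0.0157). B and plasma cell markers rose in 3 of 15 and fell in 2 (camera adjusted p = 0.603), or 5 and 4 adjusted over the list alone, with Ighm (1.35 ± 0.060), Cd79b (2.86 ± 0.15) and Blk (3.55 ± 0.60) higher and Igkc (-0.89 ± 0.17) lower. Adipocyte markers rose in 4 of 13 and fell in 4 (camera adjusted p = 0.845), with the lipid genes Cd36 (3.11 ± 0.051), Pparg (1.59 ± 0.11) and Acsl1 (1.03 ± 0.063), which macrophages also express, higher and Fabp4 (-0.84 ± 0.077) lower. Skeletal muscle markers rose in 1 of 19 and fell in 3 (camera adjusted p = 0.0674), or 0 and 2 adjusted over the list alone, with Acta1 (-0.83 ± 0.11), Mylpf (-0.77 ± 0.18) and Myh1 (-1.68 ± 0.51) lower and Myh4 (0.88 ± 0.24) higher. Skin keratinocyte markers rose in 1 of 8 and fell in 3 (camera adjusted p = 0.253), with Lgals7 (-2.17 ± 0.29), Sbsn (-0.64 ± 0.11) and Krt10 (-1.12 ± 0.34) lower. Flg had 0 reads in saline and was at least 7.39-fold higher in vanoxerine, and with Flg at that bound the list mean moved from 0.29 to -0.28, the sign of the median (-0.44). Mitochondrially encoded mRNAs rose in 2 of 13 and fell in 0 (camera adjusted p = 0.446), namely mt-Nd6 (0.98 ± 0.12) and mt-Nd5 (0.75 ± 0.092), while mt-Atp6 (-0.92 ± 0.35) and mt-Nd4l (0.52 ± 0.25) varied between replicates and did not pass. Without saline replicate 1 mitochondrially encoded mRNAs rose in 11 and fell in 1 and were called by camera (adjusted p = 0.00869), and without saline replicate 2 they rose in 4 and fell in 5 (adjusted p = 0.646). For the 19 lists given without a second count, the counts adjusted over the list alone were the same.

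At least 1 alternative ended the edgeR call or turned the sign of 34 of the 145 named genes that were called: Acsl1, Acta1, Atf7ip, Bcl2l11, Blk, Bub1b, Cbx1, Ccna2, Cd5l, Cd8a, Cldn4, Col3a1, Epcam, Flg, H2-K1, Igkc, Jun, Krt10, Krt19, Maoa, Mcm4, Myc, Myh1, Myh4, Mylpf, Nlrc5, Pfkl, Psmb10, Sbsn, Slc18a2, Sqle, Tgfb1, Tlr7 and Tyms. The calls of Acsl1, Acta1, Bcl2l11, Col3a1, Jun, Myc, Pfkl, Sqle, Tgfb1 and Tlr7 were lost with log2(TPM + 1), the length offset or both, and under none of the other alternatives.

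The authors' deposited table lists 20619 genes, of which 5844 have an adjusted p under 0.05, 3380 higher and 2464 lower in vanoxerine. Its base means lay at a median ratio of 1.00 to those of DESeq2 run here on the summed counts, and 90.9% of genes were within 5%. Among 18753 genes in both, 91.8% had the same sign as in edgeR, with a Spearman correlation of 0.850 across genes, which are not independent replicates. Both called 5186 genes, 99.8% of them in the same direction. In the authors' deposited table the log2 fold change was 3.16 for C1qa, 3.45 for Mrc1, -1.05 for Col3a1 and 6.60 for Marco. Of 152 named genes in both, 6 were at least 1 apart in log2 fold change: in the authors' deposited table Cd5l was at 0.090, Tlr7 at 0.096, Flg at 0.20, Slc18a1 at 0.48, Myh1 at -0.43 and Hmga1b at -10.6, against 4.62, 1.54, 7.47, 1.58, -1.68 and -2.50 in edgeR. Flg has no reads in saline, so its 7.47 has no fixed size, and its lower bound on the log2 scale is 2.89. Hmga1b, at 6.61 CPM in saline and 1.17 in vanoxerine here, had a base mean of 3842 in the authors' deposited table. Hspb1, at 10.3 and 1.59 CPM, had a base mean of 421 there. The Hmga1b gap therefore lies in the reads counted and not in the fitting of fold changes alone. Whether the fold changes of the authors' deposited table were shrunk or fitted with length offsets is not given in the sources used here. With the length offset, 99.2% of the 18753 genes had the same sign as in that table, more than the 91.8% of the main fit. For Ehmt2 the authors' deposited table gives -0.31 with an adjusted p of 7.97e-04, where the main edgeR test made no call. Ehmt2 was called lower by edgeR in 5 other settings, with upper-quartile factors, with library totals, at a mean CPM of at least 1, among protein-coding genes, and with the length offset (log2 fold change -0.33, adjusted p = 0.0236), and also without saline replicate 1.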

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

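This result was tested only after the data were seen: the deposited transcript files hold 1201 transcripts with no gene in the annotation used, which entered no comparison of genes, and of 308 with reads enough for the edgeR test 48 were higher and 30 lower in vanoxerine than in the saline controls.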

How the results depend on the processing

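The 12 lists called by camera were called in the same direction in each of 14 other settings of scaling, filter, test, summary, block and libraries, with 12 to 14 lists called in all except log2(TPM + 1), which called 21. Their sizes were less stable. Medians that moved by more than 1.5 times were, with log2(TPM + 1), -0.0077 for cholesterol genes, -0.011 for stress genes, -0.14 for hypoxia genes, -0.49 for fibroblast genes, -0.56 for endothelial markers, -0.44 for neutrophil markers, 0.72 for dendritic cell markers and 0.54 for nucleic acid sensing, and, with upper-quartile factors, 0.12 for nucleic acid sensing, -0.40 for hypoxia genes, -0.38 for cholesterol genes and -0.35 for stress genes. With an estimated correlation 0 lists were called (smallest unadjusted p 0.0189), and fry, which compares no list with other genes, called 24, of which 12 were not called in the main test, 10 higher and 2 lower (skeletal muscle and interferon-stimulated genes). For keratinocyte, adipocyte and interferon-stimulated genes the fry direction is opposite to the sign of the median. Of 145 named genes called, 34 lost the call or changed sign in some alternative. Same-sign losses came mostly without 1 vanoxerine library (21 and 23), with log2(TPM + 1) (19) or the length offset (16). With upper-quartile factors the median log2 fold change of all genes moved to -0.14, and 4525 genes were lower; with log2(TPM + 1) it moved to 0.13, and 870 genes were lower, 149 of them with a log2 fold change of at most -1. With the length offset 4309 genes were called, 2604 higher and 1705 lower, and 4059 of these were among the 6916. Leaving out each library gave 3107 to 9708 calls, 2113 to 5446 higher and 994 to 4262 lower, because 1 library then takes the other group's spread. Those of at least 1 in size on the log2 scale numbered 1073 to 2646, 779 to 1587 higher and 283 to 1059 lower. The Spearman correlation across genes with the authors' deposited table was 0.918 at a mean CPM of at least 1, 0.914 with the length offset, 0.942 with log2(TPM + 1), and 0.770 to 0.803 without 1 library. Other causes were not tested. Depth was alike in the 4 libraries, and genes with a few reads, such as Flg and Slc18a2, carry wide errors.

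The medians that changed sign belong to lists that were not called in the main test. With upper-quartile factors they were -0.048 for MHC class I presentation, -0.073 for H3K9 methylation and heterochromatin, -0.13 for interferon-stimulated genes and -0.078 for T cell markers. Interferon-stimulated genes were also at -0.038 with library totals, -0.033 at a mean CPM of at least 1 and -0.0075 with the length offset. T cell markers were at -0.022 with the length offset and -0.18 among protein-coding genes. Proliferation genes were at 0.016 without a filter, 0.021 with the length offset, 0.25 with log2(TPM + 1), where camera called them higher (adjusted p = 0.0489), and -0.022 to 0.035 without 1 library. B and plasma cell markers were at -0.017 at a mean CPM of at least 1, -0.013 with the length offset, and -0.052 to 0.59 without 1 library. At a mean CPM of at least 1, dopamine handling and receptors were at -0.47 and adipocyte markers at 0.59. Epithelial-mesenchymal transition genes were at -0.016 with the length offset, and mitochondrially encoded mRNAs at -0.0093 to 0.43 without 1 library. The cause was not tested.

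Lists that camera called only under alternatives were skeletal muscle markers (lower) and immediate early genes (higher), in 3 each, skin keratinocyte markers (lower), in 2, mitochondrially encoded mRNAs (higher), without saline replicate 1, and, all higher and, among the camera settings, with log2(TPM + 1) alone, genes of MHC class I presentation, cytotoxic and NK cells, checkpoints and regulatory T cells, chemokines and inflammatory cytokines, p53 targets and apoptosis, and proliferation.

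Among named genes, Ehmt1 was at -0.073 with upper-quartile factors, -0.26 with the length offset and -0.020 with log2(TPM + 1). With log2(TPM + 1), Ifit1 was at 0.21, H2-K1 at 0.041, Maoa at 0.0022, Atf7ip at -0.52 and Tyms at 0.0090, and Atf7ip was at -1.03 with the length offset. Ifit1 was at -0.17 to 0.092 without 1 library. With upper-quartile factors Mki67 was at -0.12. Mki67 was also at -0.035 with library totals, -0.030 at a mean CPM of at least 1, -0.021 among protein-coding genes and -0.00076 to 0.035 without 1 library. The cause was not tested.

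Named genes without a main call that were called under alternatives are Ehmt2, in 6 of them and lower each time, mt-Atp6, in 5 and lower each time, mt-Nd4l, in 2 and higher each time, Slc18a1, in 1 and higher, and Ifit1, in 2 with opposite signs: 0.092 without saline replicate 1 (adjusted p = 0.0244) and -0.17 without saline replicate 2 (adjusted p = 7.88e-05).

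The saline and vanoxerine libraries share replicate numbers, but the labels do not say that a number marks a shared animal, batch or day. With 2 pairs, the correlation of the deviations of same-numbered libraries was 0.010, so the numbers were not taken to pair the samples. With the replicate number as a block 6391 genes were called, 6168 of them among the 6916, and the same 12 lists.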

Other observations

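The lists and tests in this part were all chosen after the data were seen, so their counts describe these libraries and are no independent evidence. Mast cell markers rose in 9 of 10 genes, by a median log2 fold change of 2.97. They include the granule protease genes Cma1, from 3.12 ± 0.614 to 21.2 ± 1.88 CPM, Mcpt4, from 2.00 ± 0.846 to 17.0 ± 0.241 CPM, and Tpsb2, from 1.59 ± 0.448 to 15.4 ± 0.0768 CPM. Genes that the liver X receptor is known to induce rose in 7 of 10, by a median of 1.94, among them the cholesterol exporter genes Abca1, from 16.3 ± 0.154 to 139 ± 2.60 CPM, and Abcg1, from 39.5 ± 2.00 to 150.4 ± 6.75 CPM, and Lpl, from 77.2 ± 4.67 to 306 ± 3.62 CPM. Another target, Srebf1, was at 109.5 ± 1.00 CPM in saline and 105 ± 0.685 CPM in vanoxerine and did not pass the test. Genes of resident-type macrophages rose in 13 of 14 and fell in 1, by a median of 3.11, including Selenop, from 30.5 ± 2.03 to 383 ± 4.93 CPM, Stab1, from 39.9 ± 0.591 to 321 ± 5.29 CPM, and Gas6, from 3.70 ± 0.325 to 42.6 ± 0.220 CPM, while Lyve1 fell from 3.26 ± 0.346 to 1.42 ± 0.243 CPM. Monocyte-type genes rose in 6 of 12 and fell in 3, by a median of 0.20, with Plac8 at 425 ± 3.60 CPM in saline and 401 ± 7.61 CPM in vanoxerine and Il1b at 746 ± 24.8 CPM in saline and 789 ± 26.5 CPM in vanoxerine, neither called.

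Genes of fascia and dermal fibroblasts fell in 10 of 10, by a median of -2.27, against -0.87 for the fibroblast list fixed in advance, which shares Dcn with it. They include Pi16, from 17.6 ± 2.35 to 4.80 ± 0.522 CPM, and Htra3, from 7.65 ± 0.867 to 1.72 ± 0.0444 CPM. Heat shock genes fell in 9 of 11, by a median of -0.79, from the abundant Hspa8, from 3244 ± 84.5 to 2838 ± 25.3 CPM, and Hsp90aa1, from 1252 ± 19.7 to 866 ± 1.73 CPM, to Hspe1, from 344 ± 11.6 to 194 ± 2.56 CPM.

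The first pattern weighed is the higher level of macrophage, dendritic cell and MHC class II transcripts in vanoxerine. A smaller share of tumour cells alone, with the other cell types in unchanged proportions to each other, would raise their markers alike. The fibroblast list was instead at -0.87, with its upper quartile (-0.54) below 0. The lower quartile of the macrophage list (1.04) was above 0. Fewer tumour cells together with a shift among the other cell types cannot be excluded, since the share of tumour cells was not measured. Library scaling, filtering or length summary would move the macrophage median with the setting, yet its lowest value over those alternatives was 1.87, against 2.01. A difference between single tumours cannot be told apart from the treatment, since the exact permutation p of the macrophage score cannot go below 0.333 with 2 against 2 libraries. A larger share of macrophages and dendritic cells after vanoxerine, or a change of their state, may account for the pattern and stays a hypothesis.

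The second pattern is the lower level of fibroblast, endothelial and erythroid transcripts. Dilution by added macrophage RNA would lower genes of dividing cells and of fibroblasts alike, if the added cells carry no proliferation transcripts themselves. The proliferation list was at -0.00115, with its lower quartile (-0.049) above the upper quartile of the fibroblast list (-0.54). Its own median moves with the scaling, so only the gap between the lists bears on dilution. Which cells carried the proliferation transcripts was not tested, so the gap cannot exclude dilution. With upper-quartile factors the medians were -0.135 for proliferation and -0.998 for fibroblast genes. More skin, fat or muscle around the saline tumours may contribute. Camera called the muscle list (median -0.35) lower in 3 alternatives and the keratinocyte list in 2, though neither in the main test. The smallest camera adjusted p was 0.0396 for muscle and 0.0268 for keratinocyte markers. Fry called the keratinocyte and adipocyte lists higher. The 1 keratinocyte gene called higher, Flg, had 0 reads in saline and 42 in vanoxerine. The adipocyte genes called higher included Cd36, Pparg and Acsl1, which macrophages also express. In the main test members of the muscle, keratinocyte and adipocyte lists went both ways. More surrounding tissue thus cannot be told apart from a change within the tumours. Genes of fascia and dermal fibroblasts fell in 10 of 10, by a median of -2.27. That list was chosen after the data were seen, and whether its reads came from surrounding tissue was not tested. An effect of vanoxerine on tumour stroma and blood content also stays open.

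The third pattern is how closely the libraries of 1 group resemble each other. If both came from 1 tumour or 1 pool of RNA, they would share T and B cell clones, and thus variable segments. Of 27 segments with at least 100 reads in all, those with at least 20 in the pair were compared; the chi-square per degree of freedom was 14.2 within saline (26 segments) and 10.8 within vanoxerine (23), against 40.5 to 67.6 between groups (26 or 27), and the lowest value between groups was 2.86 times the highest within. Trbv26 was at 3.60 and 3.61 CPM in saline and 0.058 and 0.18 in vanoxerine, and Trbv3 at 0.22 and 0.18 against 5.63 and 6.27. Other segments split within saline, such as Trav5-4, with 0 and 69 reads, Trav9d-3, with 0 and 26, and Igkv4-72, with 84 and 21. Ighv3-6 had 108 and 39 reads there and Trbv20 158 and 70, whereas Trbv13-2 had 202 and 189. In vanoxerine the widest splits in reads were Trav7-2, with 0 and 97, and Trav7d-2, with 101 and 0. Reads shared between similar segments are uncertain. The 10.8 within vanoxerine counts Trav7-2 and Trav7d-2, so it may overstate how far those libraries differ. It was not computed without these segments. The segments with most reads in vanoxerine were Trbv3, with 390 and 413, Trbv16, with 320 and 280, and Trbv13-1, with 260 and 188. Next came Trbv13-2, with 174 and 167, and Trbv1, with 159 and 156. A shared tumour or pool may explain the resemblance within groups. The ratio, which rests on the saline value, fell short of the bound set for it. The saline value does not bear on the vanoxerine pair, for which a shared tumour or pool stays open. If it holds for a group, its 2 libraries stand for 1 tumour or pool. Separate tumours cannot be told apart from a shared tumour or pool by this test.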
